A study of Mus musculus with 35 samples.

How the data were processed

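The series holds polyadenylated RNA sequencing of 35 mouse KL lung tumors after 3 weeks of vehicle (9 libraries), trametinib (8), entinostat (9) or both drugs (9). Per the submitters' processing notes, reads were aligned to mm10 with STAR 2.5 and quantified with HOMER. Per the file headers, the deposited values are FPKM from HOMER, counted over exons with 1 transcript kept per gene. The version of HOMER and other alignment settings are not stated. The file holds 24537 rows with no repeated gene symbol. Low values, multiplied by transcript length and library total, came to whole reads within 0.1 of a read, which gave each library's depth: 3.08 to 37.9 M reads, with a median of 25.6 M. At these depths 1 read per kilobase stood at 0.0351 FPKM in vehicle replicate 1. Counting error is therefore largest in the trametinib libraries, where a median of 8943 genes were listed at 0, against 7553 with vehicle.

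Groups came from the sample titles. FPKM values were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend) on log2(FPKM + 0.5), for the 13596 genes with a mean FPKM of at least 0.5, with all 35 libraries in 1 fit and no covariate. Tests were two-sided, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Each drug and the combination were compared with vehicle, the combination was compared with each drug, and the interaction was the contrast of combination minus trametinib minus entinostat plus vehicle. The deposited scale is FPKM, so the reported fits used no count model, and voom on recovered reads served only as an alternative.

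The 32 gene lists, the comparisons, the tests, the other settings and the rule for named genes were fixed before the data were examined. A list score is the mean over members with a mean FPKM of at least 0.1 of log2(FPKM + 0.5), centred per gene. Group differences were tested with an exact two-sided permutation test of the libraries, adjusted over the 32 lists, and the interaction with 100000 permutations of the residuals of the additive model. An adjusted p shared by several lists can come from the adjustment itself. For the combination against vehicle the smallest shared adjusted p also reflects the smallest p the permutations can give. Lists described gene by gene were chosen after the list results were seen. Member counts come from the test of single genes, over all 13596 genes and adjusted over the list alone. Beside these tests stands limma's camera, with a preset correlation of 0.01 and with one estimated per list. Camera asks whether a list moved more than the other genes, while the permutation test asks whether its score differed between groups. Every adjusted p given with an estimated correlation comes from camera and answers that other question. Named genes are the 10 highest and 10 lowest fold changes past the threshold against vehicle, 5 and 5 in the other comparisons, up to 4 members of each described list, and 18 genes named in advance (Stk11, Kras, Map2k1, Map2k2, Hdac1, Hdac2, Hdac3, Dusp6, Spry4, Cd3e, Cd8a, Cxcl9, Cxcl10, Ccl5, B2m, H2-K1, Cd274 and Mki67). Symbols of the form Gm plus digits, ending in Rik, or starting with Mir, Snor or LOC were passed over.

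The procedure was tested on simulated data at the real depths before the comparisons were run. In 20 simulations with no change the highest number of false calls was 3. Of 100 genes given a log2 change of 1 beside 100 given 2, 94, 94 and 92% were recovered for trametinib, entinostat and the combination against vehicle, and 95% of the latter each time, with 12, 3 and 6 false calls among the unchanged genes. Other settings fixed in advance were the pseudocount, the filter, 3 scalings, robust and untrended eBayes, array weights, the replicate number as a block, a fit on the compared groups only, the endothelial score as a covariate, a fold minimum, and leaving out each library. After the data were seen, voom on the recovered reads, thinning of all libraries to the shallowest, and a fit without the 3 libraries under 5 M reads were added. The planned sex covariate was not run, since Xist was above 0 and 4 Y-linked genes were at 0 in all 35 libraries, and the choice between repeated symbols did not apply. Replicate numbers did not pair libraries: same-number correlations ran from -0.301 to 0.306 and 1 of 35 libraries matched its own number best, so no block was used in the reported fits. Lists and permutations were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.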

Results

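Polyadenylated RNA of 35 primary lung tumors from KL mice, a model with mutant Kras and loss of Stk11 (Lkb1), was sequenced after 3 weeks of treatment. There were 9 libraries with vehicle, 8 with the MEK inhibitor trametinib, 9 with entinostat, an inhibitor of class I histone deacetylases, and 9 with both drugs, called the combination. Doses in the labels were 1 mg/kg trametinib and 5 mg/kg entinostat, except that combination replicate 1 carried no dose label and took its group from its title. The series title frames the work around HDAC3 and the entry of T cells into Kras mutant lung tumors. Values were FPKM for 24537 genes. Depth, recovered from the values, ran from 23.2 to 32.0 M reads per vehicle library, 25.6 to 37.9 M per entinostat library, 9.91 to 32.4 M per combination library and 3.08 to 14.9 M per trametinib library. Trametinib replicates 2, 6 and 7 held under 5 M reads each. Column names carried 1 number per group (4257, 4455, 4241 and 4263 for vehicle, trametinib, entinostat and combination), and the labels do not say what it stands for. If it marks an animal, animal and treatment cannot be told apart in any comparison below. Gene positions are on mm10 as deposited, log2 fold changes carry their SE, and FPKM means carry their SD.

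Trametinib was compared with vehicle to ask what blocking MEK did to the tumors (n = 8 and 9). Targets and feedback genes of ERK, the kinase below MEK, were lower. Dusp6 (chromosome 10, 99263231 to 99267489), a phosphatase that switches ERK off, averaged 53.1 ± 4.58 FPKM with trametinib and 87.4 ± 7.29 with vehicle, a log2 fold change of -0.71 ± 0.06 (adjusted p = 5.77e-11). Falls of a like size were measured for Egr1 (-0.70 ± 0.12), Dusp5 (-0.70 ± 0.14) and Spry4 (-0.58 ± 0.10). In the ERK pathway list, 0 of 19 tested members rose and 9 fell (1 and 11 adjusted over the list alone). Its score fell by 0.30 ± 0.05 on the log2 scale, with 7 of 8 trametinib libraries below every vehicle library (exact permutation test, adjusted p = 0.00351; adjusted p = 0.204 with an estimated correlation). The drug targets themselves, Map2k1 and Map2k2, stood at 59.7 and 36.2 FPKM against 59.5 and 36.8 with vehicle, neither past the threshold, and Kras rose slightly (0.22 ± 0.05, adjusted p = 0.000806).

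**Figure D1:**
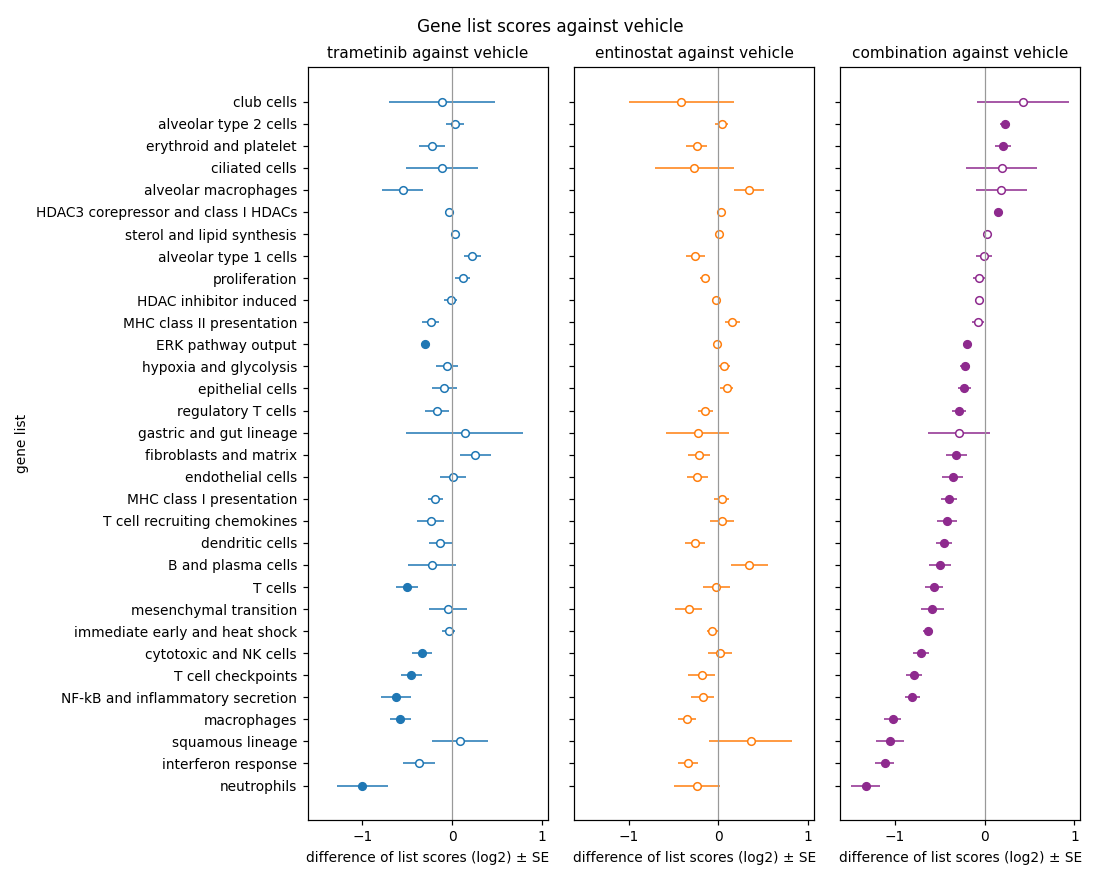
Difference of list scores from vehicle (log2, horizontal axis, bars are SE) for 32 gene lists in trametinib, entinostat and combination libraries. Filled points passed the exact permutation test after adjustment over the lists: 7 with trametinib, 0 with entinostat and 23 with the combination.

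Several inflammatory and immune lists were lower with trametinib. In the list of NF-kB targets and inflammatory secretion, 0 of 24 tested members rose and 16 fell (0 and 16 adjusted over the list alone), among them the neutrophil attractants Cxcl1 (-1.60 ± 0.19) and Cxcl2 (-1.36 ± 0.26) and the cytokines Il6 (-1.49 ± 0.20) and Il1b (-1.43 ± 0.26). The list score differed by -0.63 ± 0.16 (exact permutation test, adjusted p = 0.00948; adjusted p = 0.204 with an estimated correlation), with 7 of 8 libraries below all vehicle libraries. Neutrophil genes showed the largest list difference, from a mean score of 0.63 with vehicle to -0.37 with trametinib (standard error of the difference 0.28; exact permutation test, adjusted p = 0.0178; adjusted p = 0.386 with an estimated correlation). Of that list, 0 of 12 tested members rose and 7 fell (0 and 7 adjusted over the list alone), led by Cd177 (-2.86 ± 0.24), S100a8 (-1.71 ± 0.37), Csf3r (-1.63 ± 0.24) and S100a9 (-1.28 ± 0.34). For macrophage markers, 0 of 14 tested members rose and 12 fell (0 and 14 adjusted over the list alone), including Msr1 (-0.77 ± 0.16), the growth factor receptor Csf1r (-0.75 ± 0.09), Cd68 (-0.73 ± 0.24) and Fcgr1 (-0.70 ± 0.14). Their list differed by -0.58 ± 0.12 (adjusted p = 0.00351; adjusted p = 0.204 with an estimated correlation), with 7 of 8 libraries below all vehicle libraries. The call for Cd68 was lost without trametinib replicate 3 or 4 or vehicle replicate 1 (-0.57 to -0.66, adjusted p up to 0.0814). With voom the calls for Cd68, S100a8 and S100a9 were lost.

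T cell genes were also lower with trametinib: 0 of 21 tested members rose and 12 fell (0 and 15 adjusted over the list alone). The kinase Zap70 (-0.96 ± 0.21), the coreceptor Cd8a (-0.77 ± 0.26), the costimulator Icos (-0.77 ± 0.20) and the receptor chain Cd247 (-0.76 ± 0.20) moved most. Their list score differed by -0.50 ± 0.13 (exact permutation test, adjusted p = 0.00351; adjusted p = 0.761 with an estimated correlation), with 7 of 8 libraries below all vehicle libraries. Among cytotoxic and NK cell genes, 0 of 14 tested members rose and 2 fell (0 and 0 adjusted over the list alone), namely Gzma (-0.83 ± 0.28) and Prf1 (-0.66 ± 0.24), and the list differed by -0.33 ± 0.11 (adjusted p = 0.019; adjusted p = 0.863 with an estimated correlation). Checkpoint receptors moved by -0.45 ± 0.12 (adjusted p = 0.00658; adjusted p = 0.863 with an estimated correlation): 1 of 11 tested members rose and 4 fell (1 and 6 adjusted over the list alone), with Tnfrsf9 (-1.21 ± 0.33), Tigit (-1.003 ± 0.25), Lag3 (-0.78 ± 0.22) and Ctla4 (-0.69 ± 0.22) lowest. Also lower were Cd3e (-0.69 ± 0.22), Ccl5 (-0.65 ± 0.22) and the checkpoint ligand Cd274 (-0.69 ± 0.17), while Mki67 (0.25 ± 0.09) was higher. The proliferation list, to which Mki67 belongs, did not pass (0.12 ± 0.09, exact permutation test, adjusted p = 0.357). Not past the threshold were Cxcl9 (0.22 ± 0.26), Cxcl10 (0.13 ± 0.22), B2m (-0.06 ± 0.11) and H2-K1 (-0.13 ± 0.09). Immune lists that did not pass with trametinib were B and plasma cells (-0.22 ± 0.26), dendritic cells (-0.13 ± 0.13), regulatory T cells (-0.17 ± 0.13), alveolar macrophages (-0.55 ± 0.23) and T cell recruiting chemokines (-0.24 ± 0.15). Nor did interferon response (-0.37 ± 0.18) or MHC class I (-0.19 ± 0.08) and class II (-0.24 ± 0.09). With voom the calls for Cd8a, Icos, Cd247, Cd3e, Gzma, Ccl5 and Mki67 were lost. So were those for Tnfrsf9, Tigit, Lag3 and Ctla4. Several of the gene calls lay near the threshold and were lost without single libraries, with the fold change keeping its sign. Cd3e lost its call without trametinib replicate 1, 3 or 6 or vehicle replicate 7 (-0.56 to -0.63, adjusted p up to 0.0671). Cd8a lost it without trametinib replicate 1, 3, 5 or 6 or vehicle replicate 2 or 7 (-0.68 to -0.76, up to 0.0707), and Ctla4 without trametinib replicate 1 or 3 (-0.54 to -0.59, up to 0.0651). Ccl5 lost it without trametinib replicate 1, 3 or 6 or vehicle replicate 1 or 5 (-0.55 to -0.63, up to 0.0766), Gzma without trametinib replicate 3, 4 or 7 or vehicle replicate 4, 5, 6 or 9 (-0.57 to -0.80, up to 0.0889), and Mki67 without trametinib replicate 5, 6 or 8 or vehicle replicate 2, 3, 4 or 8 (0.21 to 0.24, up to 0.0864). Prf1 lost it without any 1 of 24 libraries (-0.55 to -0.66, up to 0.114), 14 of them entinostat or combination libraries, which left its fold change as it was.

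**Figure D2:**
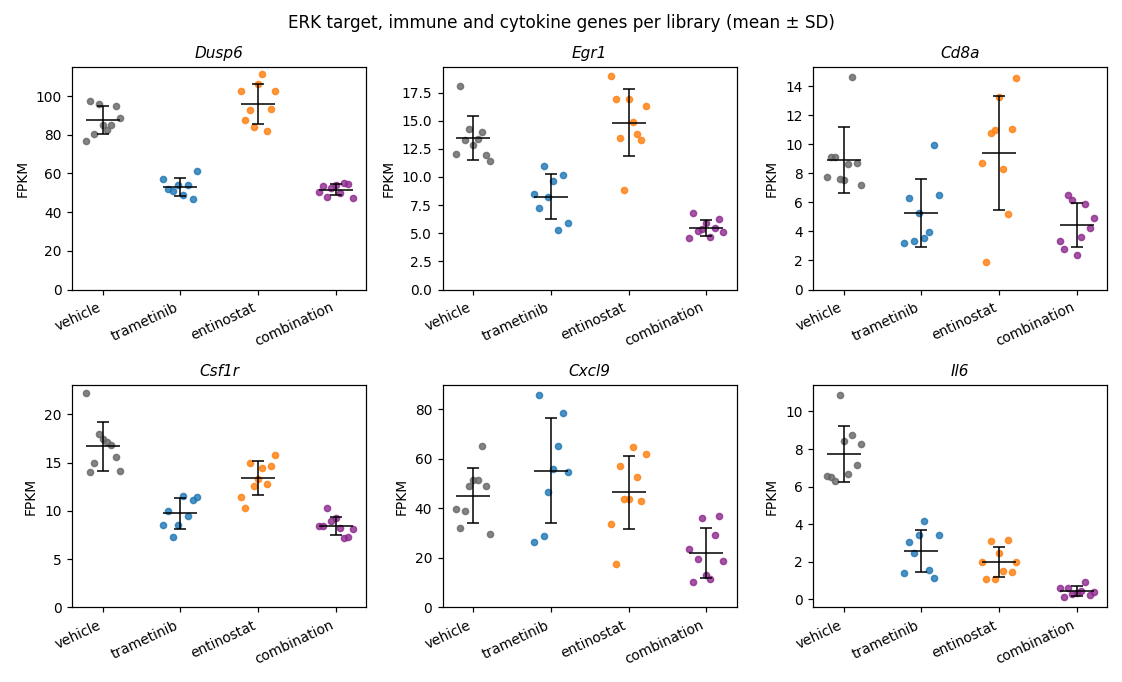
FPKM (vertical axis) of 6 genes in each library by treatment group; points are libraries and bars the mean and SD. Dusp6 averaged 87.4 with vehicle, 53.1 with trametinib, 95.9 with entinostat and 51.6 with the combination, and Il6 was lowest with the combination (mean 0.428).

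Of 13596 genes tested, 980 were higher and 1585 lower with trametinib, 140 of them by an absolute log2 fold change of at least 1. The largest rises were AA465934 (3.29 ± 0.20), the transcription factor Zbtb16 (2.96 ± 0.13), Bex2 (2.73 ± 0.30), Fam150a (2.16 ± 0.12), Zmat4 (1.83 ± 0.27) and Plxna4os1 (1.68 ± 0.12). Next came the monooxygenase Fmo4 (1.68 ± 0.24), the bone matrix protein Ibsp (1.60 ± 0.43), the guidance cue Ntn1 (1.42 ± 0.13) and Arxes2 (1.41 ± 0.19). The largest falls were the ribosomal protein Rps2 (-4.72 ± 0.11), Atp6v0c-ps2 (-3.90 ± 0.11), the proton pump subunit Atp6v0c (-3.84 ± 0.11) and Hsd17b14 (-3.44 ± 0.22). They were followed by Hmga1-rs1 (-3.02 ± 0.12), Hmga1 (-2.96 ± 0.12), Cd177, the iron reductase Cybrd1 (-2.30 ± 0.16), Phgr1 (-2.12 ± 0.34) and Ceacam10 (-1.77 ± 0.30). Rps2, and the overlapping pairs Atp6v0c with Atp6v0c-ps2 and Hmga1 with Hmga1-rs1, share sequence with other loci, so their values are uncertain. Rps2 (chromosome 17, 24720063 to 24721927) averaged 1.09 ± 0.483 FPKM with trametinib against 39.7 ± 4.81, 81 ± 6.22 and 45.1 ± 2.24 with vehicle, entinostat and the combination. Stk11 (-0.14 ± 0.08), Hdac1 (-0.07 ± 0.12) and Hdac3 (-0.07 ± 0.06) did not pass the threshold, and Hdac2 (0.16 ± 0.05) did. Hdac2 lost its call with voom, with array weights, after thinning and when fitted on these groups alone. The count of changed genes fell to 1420 when fitted on these groups alone, 1566 with voom and 1300 with all libraries thinned to one depth. The share that was higher, 38.2%, became 52.2% with quantile normalization.

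Entinostat was compared with vehicle to ask what class I deacetylase inhibition did alone (n = 9 and 9). Genes named for induction by such inhibitors did not shift as a set: 1 of 6 tested members rose and 1 fell (2 and 1 adjusted over the list alone), Gsn (-0.40 ± 0.10) falling and Txnip (0.20 ± 0.06) rising, and the list differed by -0.02 ± 0.04 (exact permutation test, adjusted p = 0.778). Genes of the HDAC3 corepressor and the class I deacetylases differed by 0.03 ± 0.02 (adjusted p = 0.417). In that list Tbl1xr1 (0.31 ± 0.06) rose and Hdac2 (-0.20 ± 0.05) fell, Hdac2 losing its call with median-ratio scaling. Macrophage markers gave the smallest p of any list, -0.35 ± 0.10 with 4 of 9 libraries below all vehicle libraries, and missed the threshold (adjusted p = 0.0908). Single members passed: C1qb (-0.56 ± 0.11), Ms4a7 (-0.56 ± 0.16), Adgre1 (-0.48 ± 0.12) and the lipid carrier Apoe (-0.46 ± 0.11) fell. Plasma cell genes Jchain (1.20 ± 0.27), Derl3 (0.74 ± 0.20) and Tnfrsf17 (0.65 ± 0.18) rose, and the B and plasma cell list as a whole differed by 0.34 ± 0.21 (adjusted p = 0.296). None of the 32 lists passed the exact permutation test, 6 had an unadjusted p under 0.05, and limma's camera passed 5 with a preset correlation and 0 with an estimated one. Leaving out vehicle replicate 2 or entinostat replicate 9 let 2 lists pass, and so did median-ratio scaling.

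The largest rises with entinostat were Bex4 (3.49 ± 0.33) and Bex2 (3.45 ± 0.29) of the X-linked Bex family, the stomach protein Gkn2 (2.66 ± 0.70), the receptor kinase Ros1 (1.99 ± 0.25) and the connexin Gja3 (1.90 ± 0.22). They were followed by Marco (1.75 ± 0.31), a scavenger receptor of alveolar macrophages, Bex1 (1.65 ± 0.28), Gsta3 (1.53 ± 0.26), the peptide hormone Apln (1.47 ± 0.30) and Parm1 (1.42 ± 0.23). Bex2 (chromosome X, 136066565 to 136068236) averaged 36.6 ± 16.7 FPKM against 3.13 ± 2.24 with vehicle. The largest falls were the mast cell protease Mcpt1 (-4.55 ± 1.27), the noncoding RNA Snhg18 (-3.26 ± 0.11), the hormone Sst (-2.93 ± 0.48) and the trefoil peptide Tff1 (-2.28 ± 0.79). Next were the deaminase Cda (-2.26 ± 0.26), Cybrd1 (-2.25 ± 0.15), Cthrc1 (-2.05 ± 0.21), the acute phase protein Saa3 (-1.82 ± 0.32), Il6 (-1.78 ± 0.19) and Retnlg (-1.76 ± 0.24). Mcpt1 ran from 0.168 to 705 FPKM among vehicle libraries, and its call was lost with voom. Tff1 lost its call without entinostat replicate 2 or vehicle replicate 1, 4, 6 or 9 (adjusted p up to 0.0807). Snhg18 (chromosome 15, 32240568 to 32244662) averaged 1.26 ± 0.484 FPKM with entinostat and between 14.8 and 20.4 in the other groups. Those groups include the combination, which also held entinostat, so the fall was not shared by both groups given this drug. Whether the fall came from entinostat or from a difference between animals was not tested. Of the genes followed in every comparison, Dusp6 (0.13 ± 0.06), Spry4 (-0.19 ± 0.10), Cd3e (-0.02 ± 0.21), Cd8a (-0.06 ± 0.25), Cxcl9 (-0.01 ± 0.25) and Cxcl10 (-0.28 ± 0.22) did not pass the threshold. Entinostat replicate 2 was far below its group for T cell genes. Without it Cd3e stood at 0.12, Cd8a at 0.18, Cxcl9 at 0.16 and the T cell list at 0.10 in place of -0.02 ± 0.15, none past the threshold. Also not past it were Ccl5 (-0.22 ± 0.21), B2m (0.01 ± 0.11), H2-K1 (0.02 ± 0.09), Cd274 (0.11 ± 0.16) and Mki67 (-0.13 ± 0.08). Stk11 (-0.06 ± 0.07), Map2k1 (0.09 ± 0.06), Map2k2 (-0.11 ± 0.05), Hdac1 (0.11 ± 0.12) and Hdac3 (-0.03 ± 0.06) did not pass either, and Kras (0.14 ± 0.04) did. In all, 720 genes were higher and 3113 lower. This balance rested on the scaling: 1590 were higher and 1368 lower with median-ratio scaling, and 1274 and 1323 with quantile normalization. Only 95 of the 3833 had an absolute log2 fold change of at least 1, and the count was 2272 after thinning.

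The combination was compared with vehicle to ask what both drugs did together (n = 9 and 9). Genes induced by interferon were lower: 0 of 21 tested members rose and 20 fell (0 and 20 adjusted over the list alone). The largest falls in this list were Usp18 (-1.99 ± 0.25), Ifit1 (-1.68 ± 0.30), Irf7 (-1.67 ± 0.25) and Isg15 (-1.64 ± 0.26). The list score fell by 1.12 ± 0.11 on the log2 scale and all 9 combination libraries lay below every vehicle library (exact permutation test, adjusted p = 0.00012; adjusted p = 0.373 with an estimated correlation). Genes of antigen presentation by MHC class I were lower too: 0 of 17 tested members rose and 16 fell (0 and 16 adjusted over the list alone), with the regulator Nlrc5 (-0.72 ± 0.15), the peptide transporter genes Tap1 (-0.63 ± 0.13) and Tap2 (-0.54 ± 0.10) and the chaperone Tapbp (-0.58 ± 0.08). That list differed by -0.40 ± 0.09 (adjusted p = 0.00149; adjusted p = 0.628 with an estimated correlation), and B2m (-0.36 ± 0.11) and H2-K1 (-0.33 ± 0.09) fell. Of the list named T cell recruiting chemokines, Cxcl9 (-1.11 ± 0.25), Cxcl10 (-0.997 ± 0.22), Ccl5 (-1.60 ± 0.21) and Cxcl13 (-1.29 ± 0.52) fell. In their list, 1 of 15 tested members rose and 9 fell (2 and 9 adjusted over the list alone), and the score differed by -0.42 ± 0.11 (adjusted p = 0.00271; adjusted p = 0.782 with an estimated correlation). Leaving out any 1 of 12 libraries ended the call for Cxcl13 (adjusted p up to 0.08), and H2-K1 lost its call with quantile normalization.

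Immune cell markers were lower with the combination. For T cells, 0 of 21 tested members rose and 17 fell (0 and 19 adjusted over the list alone), with Cd8b1 (-1.002 ± 0.22), Cd8a (-0.97 ± 0.25), Cd2 (-0.74 ± 0.16) and Cd3g (-0.73 ± 0.21) lowest and Cd3e (-0.69 ± 0.21) also down. That list differed by -0.56 ± 0.10 and every combination library lay below every vehicle library (exact permutation test, adjusted p = 0.00012; adjusted p = 0.628 with an estimated correlation). Killing genes fell, Gzma (-1.79 ± 0.27), Prf1 (-1.30 ± 0.23), Nkg7 (-1.16 ± 0.22) and the NK receptor Ncr1 (-1.04 ± 0.18) most. Of the cytotoxic and NK list, 0 of 14 tested members rose and 9 fell (0 and 9 adjusted over the list alone), a list difference of -0.71 ± 0.09 (adjusted p = 0.00012; adjusted p = 0.519 with an estimated correlation). All 14 tested macrophage markers fell, over all genes and adjusted over the list alone, with Apoe (-1.38 ± 0.11), Fcgr1 (-1.28 ± 0.13), Msr1 (-1.27 ± 0.16) and C1qb (-1.20 ± 0.11) lowest. Their list differed by -1.03 ± 0.09 (adjusted p = 0.00012; adjusted p = 0.297 with an estimated correlation). Neutrophil genes differed by -1.33 ± 0.16 (adjusted p = 0.00012; adjusted p = 0.376 with an estimated correlation), and 0 of 12 tested members rose and 9 fell (0 and 10 adjusted over the list alone), including Cd177 (-2.34 ± 0.24), Retnlg (-2.33 ± 0.24), Csf3r (-1.77 ± 0.23) and Cxcr2 (-1.66 ± 0.26). In the NF-kB list, 0 of 24 tested members rose and 17 fell (0 and 19 adjusted over the list alone), with Il6 (-3.17 ± 0.19), Saa3 (-2.27 ± 0.32), Il1b (-1.76 ± 0.26) and Ccl2 (-1.62 ± 0.28). Il6 (chromosome 5, 30013114 to 30019975) averaged 0.428 ± 0.25 FPKM against 7.72 ± 1.49. The NF-kB list differed by -0.80 ± 0.09 (adjusted p = 0.00012; adjusted p = 0.373 with an estimated correlation).

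Stress, ERK and lineage genes moved in both directions. Immediate early and heat shock genes are made by many cell types and also respond to handling of tissue, on which the labels give nothing and which was not tested. In the list of immediate early and heat shock genes, 1 of 12 tested members rose and 9 fell (1 and 10 adjusted over the list alone), the chaperones Hspa1b (-1.86 ± 0.19) and Hspa1a (-1.49 ± 0.19) and the transcription factors Egr1 (-1.22 ± 0.12) and Atf3 (-0.95 ± 0.12) most. All 9 libraries lay below every vehicle library (-0.63 ± 0.05, adjusted p = 0.00012 by an exact permutation test; adjusted p = 0.297 with an estimated correlation). ERK output differed by -0.20 ± 0.03 (adjusted p = 0.000506; adjusted p = 0.834 with an estimated correlation). Of its members 3 rose and 8 fell, 4 and 9 adjusted over the list alone. Falls were measured for Myc (-1.27 ± 0.24), Egr1, Fosl1 (-0.94 ± 0.24), Dusp5 (-0.80 ± 0.14), Dusp6 (-0.75 ± 0.06) and Spry4 (-0.29 ± 0.10). Etv5, which also belongs to the alveolar type 2 list, was among the rises (0.74 ± 0.09). The squamous list fell (-1.05 ± 0.16, adjusted p = 0.00012 by an exact permutation test; adjusted p = 0.669 with an estimated correlation). Of its 6 tested members 2 fell, also adjusted over the list alone: the envelope protein genes Ivl (-4.30 ± 0.32) and Sprr1a (-1.995 ± 0.36). Alveolar type 2 genes were higher (0.23 ± 0.06, adjusted p = 0.00149; adjusted p = 0.669 with an estimated correlation): 5 of 14 tested members rose and 1 fell (5 and 1 adjusted over the list alone), with the lysozyme Lyz1 (1.02 ± 0.39), Etv5 (0.74 ± 0.09), the surfactant gene Sftpc (0.57 ± 0.14) and the lineage factor Nkx2-1 (0.50 ± 0.09). Lyz1 lost its call without combination replicate 2 or 5 or vehicle replicate 4, 5 or 6 (adjusted p up to 0.0691), and Sftpc with quantile normalization.

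**Figure D3:**
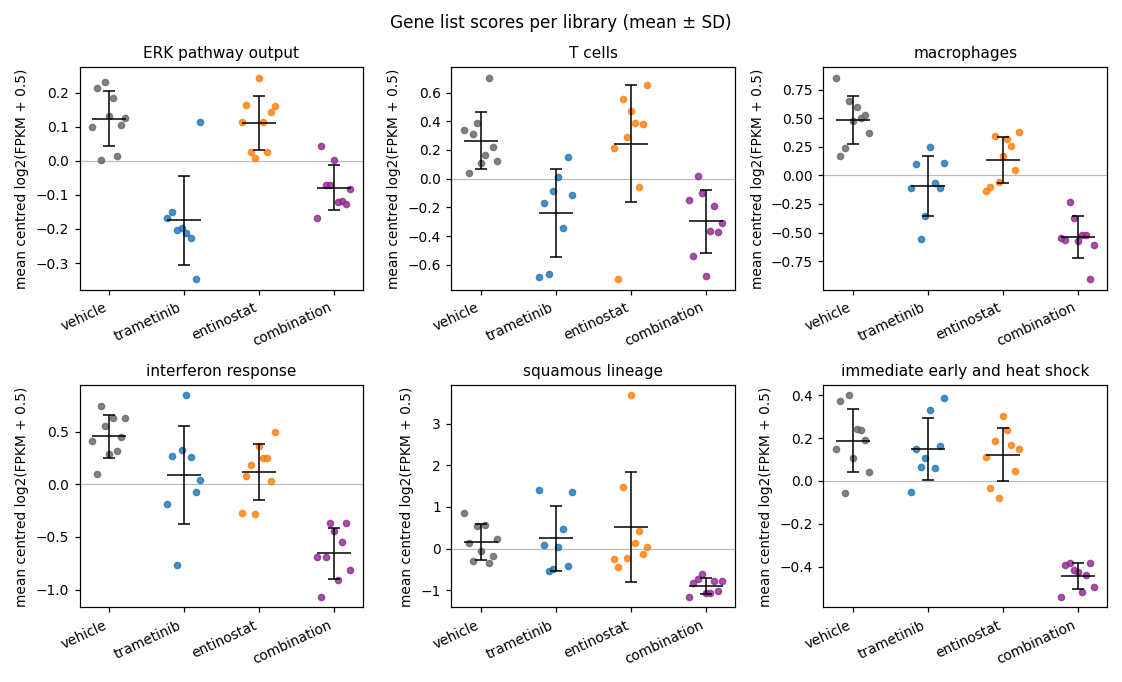
Scores of 6 gene lists (mean centred log2(FPKM + 0.5) of the members, vertical axis) in each library by group; points are libraries and bars the mean and SD. For the interferon, T cell, macrophage, squamous and immediate early lists, all 9 combination libraries lie below every vehicle library.

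Other lists that passed for the combination against vehicle were checkpoints (-0.79 ± 0.09, adjusted p = 0.00012), regulatory T cells (-0.28 ± 0.07, 0.00367) and B and plasma cells (-0.50 ± 0.13, 0.003), all by an exact permutation test. Dendritic cells (-0.46 ± 0.09, 0.000506) and endothelial cells (-0.36 ± 0.12, 0.0176) passed by the permutation test too. The same test passed for fibroblasts and matrix (-0.32 ± 0.12, 0.0257), epithelial cells (-0.22 ± 0.07, 0.00684), mesenchymal transition (-0.58 ± 0.13, 0.00012) and hypoxia and glycolysis (-0.22 ± 0.05, 0.00271). Higher with the combination were the erythroid and platelet list (0.21 ± 0.09, 0.0472 by an exact permutation test), which lost its call without any 1 of 14 libraries (adjusted p up to 0.094), and the HDAC3 corepressor list (0.15 ± 0.02, 0.00012). In camera with an estimated correlation none of these 23 lists passed, with adjusted p from 0.297 to 0.859. With the preset correlation camera passed 11 lists. The lists that did not pass were alveolar macrophages (0.19 ± 0.28), alveolar type 1 cells (-0.01 ± 0.09), club cells (0.43 ± 0.51), ciliated cells (0.19 ± 0.39), gastric and gut lineage (-0.29 ± 0.35), proliferation (-0.06 ± 0.07) and MHC class II (-0.07 ± 0.07). Neither did HDAC inhibitor induced genes (-0.06 ± 0.04) or sterol and lipid synthesis (0.03 ± 0.03).

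The largest rises with the combination were Bex2 (5.40 ± 0.29), Bex4 (5.20 ± 0.33), Ros1 (3.14 ± 0.25), Bex1 (3.03 ± 0.28) and Crym (2.72 ± 0.24). Next were Prss35 (2.34 ± 0.23), Gkn2 (2.33 ± 0.70), the arginase Arg1 (2.31 ± 0.22), the cadherin Cdh16 (2.24 ± 0.23) and Epb41l3 (2.17 ± 0.18). Bex2 averaged 133 ± 22.1 FPKM with the combination. The largest falls were Mcpt1 (-5.98 ± 1.27), Ivl, Sst (-3.98 ± 0.48), the tryptophan enzyme Ido1 (-3.84 ± 0.74) and Il6. They were followed by the chemokine Ccl8 (-3.09 ± 0.30), the basophil protease Mcpt8 (-2.82 ± 0.68), Nov (-2.70 ± 0.20), Tff1 (-2.65 ± 0.79) and Ptgs2 (-2.57 ± 0.18), which makes prostaglandins. Mcpt1 and Tff1 lost their calls with voom. Kras (0.45 ± 0.04), Hdac2 (0.16 ± 0.05) and Hdac3 (0.25 ± 0.06) were higher, and Cd274 (-0.58 ± 0.16) and Mki67 (-0.27 ± 0.08) lower. Hdac2 lost its call after rescaling to TPM and after thinning. Stk11 (-0.01 ± 0.07), Map2k1 (0.01 ± 0.06), Map2k2 (-0.11 ± 0.05) and Hdac1 (0.25 ± 0.12) did not pass the threshold. In total 2391 genes were higher and 3800 lower, and 453 changed by an absolute log2 fold change of at least 1. The higher share, 38.6%, was 27.3% after rescaling each library to the same sum (TPM) and 52.5% with quantile normalization.

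**Figure D4:**
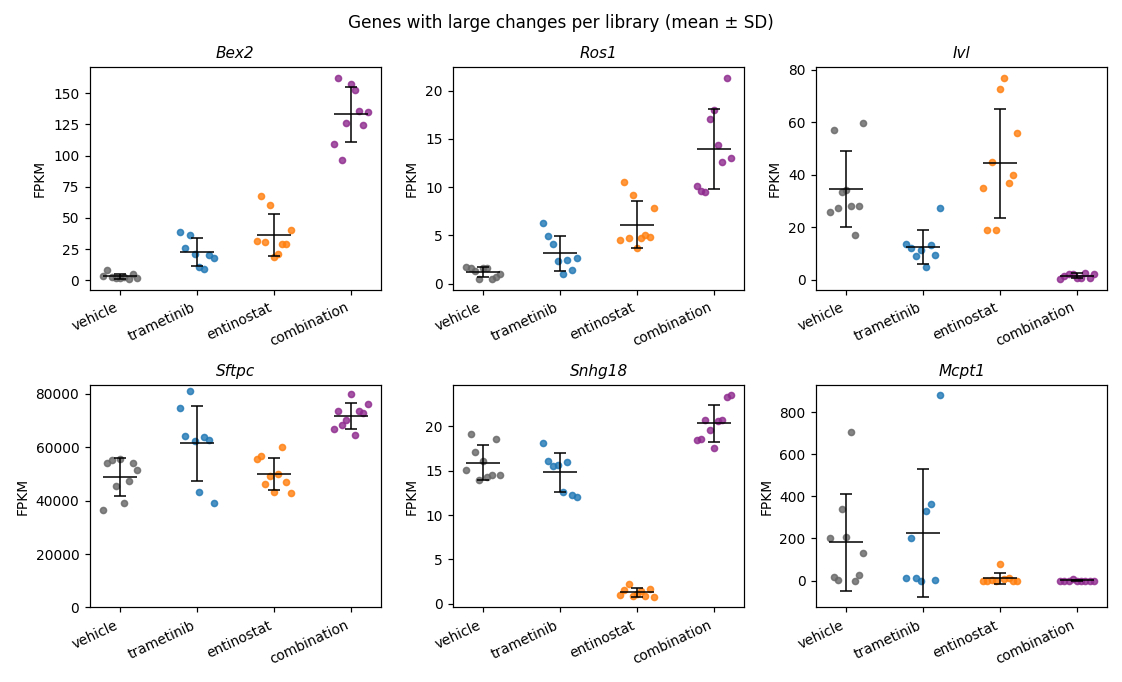
FPKM (vertical axis) of 6 genes in each library by group; points are libraries and bars the mean and SD. Bex2 and Ros1 were highest with the combination, Ivl was lowest there (mean 1.40), Snhg18 was low with entinostat only (mean 1.26), and Mcpt1 varied from 0.168 to 705 among vehicle libraries.

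Against trametinib alone, the combination asked what adding entinostat changed (n = 9 and 8). Stromal genes were lower: in the fibroblast and matrix list 0 of 15 tested members rose and 11 fell (0 and 12 adjusted over the list alone), with Pdgfra (-0.98 ± 0.17), Col3a1 (-0.95 ± 0.26), Mfap5 (-0.82 ± 0.20) and Col5a1 (-0.78 ± 0.17). That list differed by -0.58 ± 0.15 (exact permutation test, adjusted p = 0.00373; adjusted p = 0.775 with an estimated correlation). The endothelial list differed by -0.37 ± 0.14 (adjusted p = 0.0404; adjusted p = 0.775 with an estimated correlation) and lost its call without any 1 of 11 libraries (up to 0.0775); with its score as a covariate Col3a1, Mfap5, Fn1 (-0.56 ± 0.17) and Hmga2 (-1.90 ± 0.61) lost theirs. In the mesenchymal list (-0.54 ± 0.17, adjusted p = 0.00373; adjusted p = 0.775 with an estimated correlation) 1 of 9 tested members rose and 6 fell (1 and 7 adjusted over the list alone), Itgb3 (-1.12 ± 0.26) among the falls and S100a4 (0.43 ± 0.18) the rise. S100a4 lost its call without any 1 of 11 libraries (adjusted p up to 0.11). Hemoglobin and platelet genes were higher, Pf4 (1.04 ± 0.18), Hbb-bs (0.84 ± 0.14), Hbb-bt (0.82 ± 0.29) and Hba-a1 (0.76 ± 0.15). Of that list 6 of 7 tested members rose and 0 fell (6 and 1 adjusted over the list alone), and it differed by 0.43 ± 0.13 (adjusted p = 0.00373; adjusted p = 0.756 with an estimated correlation). Hbb-bt fell to 0.46 and lost its call without trametinib replicate 7, where it was listed at 0 (adjusted p = 0.0602).

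In this comparison the interferon list was again lower (-0.75 ± 0.18, adjusted p = 0.00489 by an exact permutation test; adjusted p = 0.775 with an estimated correlation). The chemokines Cxcl9 (-1.33 ± 0.26), Cxcl10 (-1.12 ± 0.22) and Ccl5 (-0.95 ± 0.22) fell, but their list, of which 2 of 15 tested members rose and 5 fell (2 and 5 adjusted over the list alone), did not pass (-0.18 ± 0.17, adjusted p = 0.359 by the same permutation test). T cell genes differed by -0.06 ± 0.13 (adjusted p = 0.66 by the same permutation test), and Cd8a (-0.20 ± 0.26) and Cd3e (adjusted p = 0.998) did not pass. Lists that also passed were macrophages (-0.45 ± 0.11), dendritic cells (-0.32 ± 0.11), squamous lineage (-1.14 ± 0.29), immediate early and heat shock (-0.60 ± 0.06) and the HDAC3 corepressor (0.19 ± 0.04). Cytotoxic and NK cells (-0.37 ± 0.12), checkpoints (-0.33 ± 0.12) and alveolar type 2 cells (0.19 ± 0.09) passed as well, but lost their calls without any 1 of 5, 8 and 12 libraries (adjusted p up to 0.0605, 0.0753 and 0.0884). The alveolar type 2 difference shrank to 0.13 without trametinib replicate 8. In camera with an estimated correlation none of these 13 lists passed (adjusted p from 0.636 to 0.775). The largest rises were Rps2 (4.91 ± 0.11), Bex4 (4.17 ± 0.34), Atp6v0c-ps2 (3.51 ± 0.11), Atp6v0c (3.46 ± 0.11) and Marco (3.18 ± 0.32). The largest falls were Mcpt1 (-5.77 ± 1.30), Ido1 (-3.91 ± 0.76), Zbtb16 (-3.28 ± 0.13), Sst (-3.24 ± 0.49) and Ivl (-2.83 ± 0.33). Hdac3 (0.32 ± 0.06), Hdac1 (0.32 ± 0.12), Kras (0.23 ± 0.05) and Spry4 (0.30 ± 0.10) were higher and Mki67 (-0.52 ± 0.09) and B2m (-0.30 ± 0.11) lower. Hdac1 lost its call without combination replicate 3 or 9 or trametinib replicate 1 or 4 (0.17 to 0.30, the lowest without trametinib replicate 4, adjusted p up to 0.106). Spry4 lost it without trametinib replicate 5 or 7 (both 0.22, up to 0.0532) and B2m without combination replicate 2 or trametinib replicate 7 (-0.22 and -0.26, up to 0.0691). Dusp6 (-0.04 ± 0.06), H2-K1 (-0.21 ± 0.09), Cd274 (0.11 ± 0.17), Stk11 (0.13 ± 0.08), Map2k1 (0.01 ± 0.06) and Map2k2 (-0.09 ± 0.05) did not pass, nor did Hdac2 (adjusted p = 0.948). In total 2833 genes were higher and 3250 lower. The higher share, 46.6%, was 50.8% with median-ratio scaling, 50.3% with quantile normalization and 37.7% after rescaling each library to the same sum (TPM).

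Against entinostat alone, the combination asked what adding trametinib changed (n = 9 and 9). B and plasma cell genes were lower: 0 of 15 tested members rose and 8 fell (0 and 8 adjusted over the list alone), with Pou2af1 (-1.73 ± 0.29), Mzb1 (-1.69 ± 0.24), Jchain (-1.60 ± 0.27) and Derl3 (-1.20 ± 0.20) lowest, and the list differed by -0.84 ± 0.21 (exact permutation test, adjusted p = 0.00243; adjusted p = 0.208 with an estimated correlation). Glycolysis and hypoxia genes were lower, among them the glucose transporter Slc2a1 (-0.67 ± 0.14), Ndrg1 (-0.65 ± 0.18) and the enzymes Pkm (-0.58 ± 0.11) and Hk2 (-0.52 ± 0.09). Of that list 1 of 18 tested members rose and 8 fell (1 and 9 adjusted over the list alone), a difference of -0.28 ± 0.06 (adjusted p = 0.000329; adjusted p = 0.249 with an estimated correlation). T cell genes were lower by this contrast (-0.54 ± 0.16, adjusted p = 0.00872 by an exact permutation test; adjusted p = 0.208 with an estimated correlation), with Cd3e (-0.66 ± 0.21) and Cd8a (-0.91 ± 0.25). Interferon genes (-0.78 ± 0.12, adjusted p = 0.000219; adjusted p = 0.143 with an estimated correlation) were lower in all 9 combination libraries than in any entinostat library. In all 21 lists passed, and 1, immediate early and heat shock genes (-0.57 ± 0.05), also passed with an estimated correlation (adjusted p = 0.00917). The calls for alveolar type 1 cells (0.25 ± 0.10) and MHC class II (-0.23 ± 0.09) were lost without any 1 of 9 and 6 libraries (adjusted p up to 0.0781 and 0.0637).

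The largest rises in the combination over entinostat were Snhg18 (3.61 ± 0.11), Crym (2.61 ± 0.24), Cthrc1 (2.20 ± 0.21), angiotensinogen, Agt (2.16 ± 0.24), and Bex2 (1.95 ± 0.29). The largest falls were Ivl (-4.61 ± 0.32), Cd177 (-3.61 ± 0.24), Sprr2a3 (-2.46 ± 0.56), the protease Prss22 (-2.34 ± 0.34) and Ido1 (-2.33 ± 0.74), the last lost with voom. Dusp6 (-0.88 ± 0.06), Cxcl9 (-1.11 ± 0.25), Cxcl10 (-0.71 ± 0.22), Ccl5 (-1.38 ± 0.21), B2m (-0.37 ± 0.11), H2-K1 (-0.35 ± 0.09) and Cd274 (-0.69 ± 0.16) fell, and Kras (0.32 ± 0.04), Hdac2 (0.36 ± 0.05) and Hdac3 (0.28 ± 0.06) rose. Stk11 (0.05 ± 0.07), Map2k1 (-0.08 ± 0.06), Hdac1 (0.13 ± 0.12), Spry4 (-0.09 ± 0.10) and Mki67 (-0.14 ± 0.08) did not pass, nor did Map2k2 (adjusted p = 0.96), and H2-K1 lost its call with quantile normalization. In total 3135 genes were higher and 1810 lower, a higher share of 63.4% that became 45.9% with median-ratio scaling and 45.3% after rescaling each library to the same sum (TPM).

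The interaction asked whether the effect of one drug depended on the other (35 libraries). Immediate early and heat shock genes departed from additivity on the log2 scale by -0.53 ± 0.08 (permutation test, adjusted p = 0.00032; adjusted p = 0.00938 with an estimated correlation), with Hspa1b (-1.49 ± 0.27), Hspa1a (-0.97 ± 0.28), Jun (-0.74 ± 0.09) and Hsp90aa1 (-0.71 ± 0.12). The squamous list departed by -1.50 ± 0.54 (adjusted p = 0.0139; adjusted p = 0.466 with an estimated correlation), with Ivl (-3.14 ± 0.46) and Sprr1a (-1.73 ± 0.52). Hemoglobin genes Hbb-bs (1.45 ± 0.19), Hbb-bt (1.23 ± 0.41), Hba-a1 (1.22 ± 0.22) and Hba-a2 (1.21 ± 0.22) were higher than additive, and the erythroid and platelet list departed by 0.67 ± 0.17 (adjusted p = 0.00272; adjusted p = 0.466 with an estimated correlation). The HDAC3 corepressor list departed by 0.16 ± 0.04 (adjusted p = 0.00416; adjusted p = 0.707 with an estimated correlation), with Hdac3 (0.35 ± 0.08), Tbl1xr1 (0.24 ± 0.08) and Hdac2 (0.20 ± 0.07). The interferon, macrophage and T cell lists did not pass (-0.41 ± 0.21, -0.10 ± 0.15 and -0.04 ± 0.20). The squamous call was lost with the median over members (adjusted p = 0.275), with genes scaled to unit SD (0.108) and with a pseudocount of 0.1 (0.0983). The HDAC3 corepressor call was lost with the median over members (0.0991), median-ratio scaling (0.0915) and thinning (0.185). Tbl1xr1 and Hdac2 lost their calls without any 1 of 17 and 13 libraries (adjusted p up to 0.0647 and 0.0693).

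Single genes farthest above additivity were Rps2 (3.88 ± 0.16), Snhg18 (3.71 ± 0.16), Atp6v0c-ps2 (2.72 ± 0.15), Atp6v0c (2.66 ± 0.16) and Cthrc1 (2.56 ± 0.30), and those farthest below were Zbtb16 (-3.78 ± 0.19), Ivl, AA465934 (-2.81 ± 0.27), Sprr2a3 (-2.39 ± 0.80) and Fam150a (-2.20 ± 0.16). Sprr2a3 lost its call without any 1 of 7 libraries (adjusted p up to 0.0556). Cxcl9 (-1.33 ± 0.36), Mki67 (-0.39 ± 0.12) and Spry4 (0.49 ± 0.14) passed the threshold, and Cxcl9 and Mki67 did not without the 3 libraries under 5 M reads. Mki67 also lost its call with array weights and after thinning, and Spry4 with quantile normalization and after thinning. The proliferation list, to which Mki67 belongs, did not depart from additivity (-0.03 ± 0.10, permutation test, adjusted p = 0.938). Dusp6 (-0.17 ± 0.08), Kras (0.09 ± 0.06), Stk11 (0.19 ± 0.11), Hdac1 (0.20 ± 0.17), Cd3e (0.03 ± 0.31) and Cd8a (-0.14 ± 0.36) did not pass. Nor did Cxcl10 (-0.84 ± 0.31), Ccl5 (-0.73 ± 0.30), B2m (-0.31 ± 0.15), H2-K1 (-0.23 ± 0.13), Map2k1 (-0.08 ± 0.09), Map2k2 (0.02 ± 0.08) or Cd274 (adjusted p = 0.995). In total 1969 genes lay above and 706 below additivity. The share above, 73.6%, was 48.0% with median-ratio scaling, 51.2% with quantile normalization and 59.3% after rescaling each library to the same sum (TPM), and the count was 1313 after thinning.

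**Figure D5:**
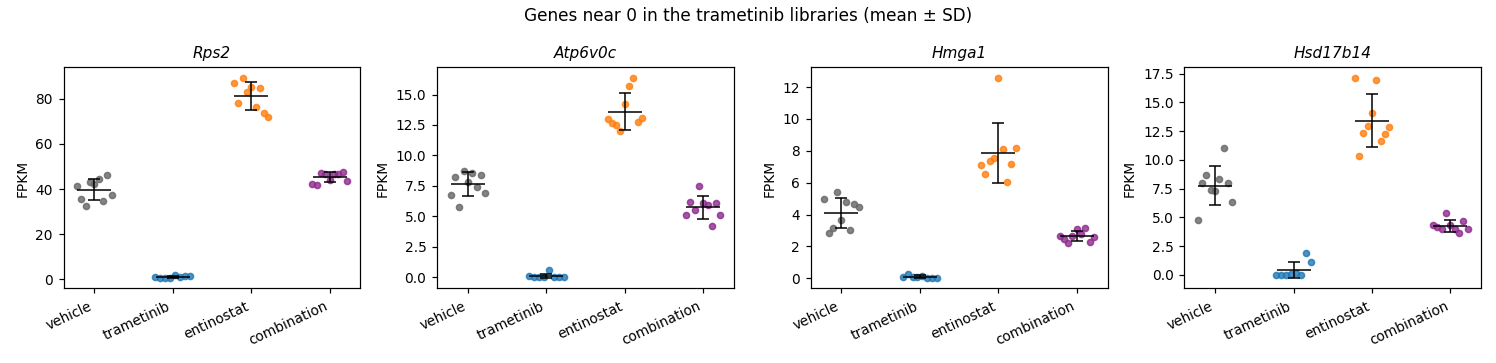
FPKM (vertical axis) of Rps2, Atp6v0c, Hmga1 and Hsd17b14 in each library by group; points are libraries and bars the mean and SD. All 4 genes were near 0 in the trametinib libraries (Rps2 mean 1.09) and highest with entinostat (Rps2 mean 81.0).

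Effects of the drugs were compared across the 13596 genes, which are not independent replicates and share the vehicle libraries. Fold changes with trametinib and with entinostat correlated at r = 0.0868, where unchanged groups simulated at the same depths gave 0.424 from the shared vehicle libraries alone. With vehicle libraries split between the comparisons, r averaged 0.00524. Fold changes with the combination correlated with those of trametinib at 0.366 (0.432 simulated, 0.291 with split vehicle libraries) and with those of entinostat at 0.583 (0.496 simulated, 0.490 split). Shared libraries add the same covariance with or without drug effects, so covariances were set beside the simulated ones. They were 0.00681 against 0.00865 for trametinib and entinostat, 0.0451 against 0.00901 for trametinib and the combination, and 0.0656 against 0.00867 for entinostat and the combination. The simulation added counting noise to a measured spread, pooled over all groups, that already held it. Its covariances may therefore be too large, and the first pair does not show opposed effects. With split vehicle libraries the covariances were 0.000355, 0.0380 and 0.0588 in the same order.

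Overlaps of the calls were set beside the number that independent calls would share. Unchanged groups in simulation shared 0. That value was fixed by their few calls (at most 3 in any comparison), so it does not measure overlap from shared libraries. For trametinib and entinostat 142 genes were higher with both (51.9 if independent), 373 were lower with both (362.9 if independent) and 330 changed in opposite directions. Trametinib and the combination shared 361 higher genes (172.3 if independent) and 827 lower ones (443 if independent), with 299 in opposite directions. Entinostat and the combination shared 484 higher genes (126.6 if independent) and 1750 lower ones (870.1 if independent), with 161 in opposite directions. Part of each overlap may come from the shared vehicle libraries.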

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

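The tests of splits, of depth as the whole source of the trametinib calls, of the position on chromosome 17 and of the numbers in the column names were chosen after the result was seen; the other tests were set before. With 720 groups tested, 72 values (10.0%) stood apart from the rest of their group, where chance gives about 1 in 20. Each value below is the gap of log2(FPKM + 0.5), or of a list score, to the nearest library over the range of the group, with the side on which the library lay.

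Entinostat replicate 2 stood apart 16 times: B2m (0.543, low), Cd247 (0.615, low), Cd8b1 (0.652, low), Cxcl9 (0.501, low), H2-K1 (0.623, low), Icos (0.618, low), Kras (0.542, high), Lag3 (0.607, low), Nkg7 (0.613, low), Tff1 (0.642, low), Tigit (0.626, low), Tnfrsf9 (0.508, low), T cell checkpoints (0.654, low), MHC class I presentation (0.618, low), MHC class II presentation (0.539, low), T cell recruiting chemokines (0.566, low). Trametinib replicate 8 stood apart for Gkn2 (0.609, high), Prss22 (0.573, high), Slc2a1 (0.584, high), ciliated cells (0.598, high), epithelial cells (0.783, high), gastric and gut lineage (0.583, high), ERK pathway output (0.575, high), HDAC inhibitor induced (0.636, high), hypoxia and glycolysis (0.741, high). Vehicle replicate 7 did so for Cd3g (0.644, high), Cd8a (0.671, high), Cd8b1 (0.5259, high), Cthrc1 (0.496, low), Ibsp (0.715, high), Nkg7 (0.624, high), MHC class II presentation (0.568, high). Vehicle replicate 1 did so for Adgre1 (0.513, high), Gsta3 (0.507, high), Hbb-bs (0.494, high), Saa3 (0.671, high), club cells (0.597, high), ciliated cells (0.757, high). In vehicle replicate 2 the values were Ccl8 (0.513, low), Egr1 (0.5261, high), Hspa1b (0.53, high). The other vehicle values were Bex1 (0.543, high) in replicate 5, Gkn2 (0.685, high) in replicate 6 and Agt (0.705, high) in replicate 9. Among other trametinib libraries these were, in replicate 1, Lag3 (0.535, low) and, in replicate 3, Cd274 (0.543, low). Trametinib replicate 5 added Atp6v0c (0.74, high), Atp6v0c-ps2 (0.693, high), and replicate 7 added Cthrc1 (0.662, low), Hbb-bt (0.589, low), Ncr1 (0.61, high). Among other entinostat libraries they were, in replicate 3, club cells (0.635, high), ciliated cells (0.884, high) and, in replicate 4, Egr1 (0.533, low), Prss35 (0.608, high), sterol and lipid synthesis (0.522, high). Entinostat replicate 5 added Hmga1 (0.587, high), Hmga1-rs1 (0.587, high), Hmga2 (0.644, high), squamous lineage (0.533, high), and replicate 8 added Cda (0.599, high). For the combination they were, in replicate 1, Ccl8 (0.533, high), in replicate 4, Mcpt1 (0.836, high) and, in replicate 5, Ifit1 (0.564, high), Itgb3 (0.518, high), Jun (0.597, high). Combination replicate 8 added Csf3r (0.52, low), Gkn2 (0.578, high), Msr1 (0.584, low), gastric and gut lineage (0.548, high), and replicate 9 added Ccl2 (0.625, low), Gsta3 (0.517, low).

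The effect of one drug differed with the other for 2675 genes and for 4 lists: squamous lineage (-1.50), erythroid and platelet (0.67), HDAC3 corepressor and class I HDACs (0.16) and immediate early and heat shock (-0.53, all log2). With an estimated correlation only the last list passed.

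For each count of changed genes, 100 splits of the libraries were fitted. The real split (1 of 100) was the only one with as many genes, which argues against chance placement of single libraries as the source. Libraries were exchanged as independent units, and each group carried 1 number in the column names. If that number marks an animal, the splits cannot exclude chance differences between animals. The highest other split gave 2041 genes against 2565 for trametinib and vehicle, 1 against 3833 for entinostat and vehicle, 1212 against 6191 for the combination and vehicle, 2569 against 6083 for the combination and trametinib, 0 against 4945 for the combination and entinostat, and 0 against 2675 for the interaction. The split with 2041 genes placed 16 of 17 libraries as in the real groups.

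First, 17 genes were near 0 (under 2 FPKM) in every library of 1 group and above 4 FPKM in every library of another, 6 of them near 0 with trametinib: Rps2, Atp6v0c, Atp6v0c-ps2, Hmga1, Hmga1-rs1 and Hsd17b14. Depth and a change in how reads shared with pseudogenes were counted are argued against: the median log2 difference was 3.28 and stayed at 3.19 after thinning, and 73 ribosomal protein genes had a median log2 fold change of 0.065 with trametinib. Strain or animal variants were predicted to cluster the 200 genes that separate the groups most, and that prediction failed (65 pairs within 2 Mb against 61.8 at random, permutation p = 0.364). That test excludes nothing for these loci: chromosome 17 from 20 to 30 Mb was left out, with 3 of the 4 separate loci near 0 with trametinib, and only 10 of the 200 genes belong to the 17. A variant on chromosome 17 stays open: these 3 loci lie within 3.4 Mb, which was noticed in these data and may reflect 1 inherited segment. A fall wherever trametinib was given is argued against, since the combination also held it. For each of the 6 genes every combination library lay above every trametinib library. Rps2 ran from 41.8 to 47.35 against 0.463 to 1.751 FPKM, and Hmga1 from 2.242 to 3.172 against 0 to 0.28. Drug action that depends on entinostat was not tested apart from a variant. Each group carried 1 number in the column names, so these explanations cannot be told apart for these loci. A count of pairs over the whole genome may also miss single segments elsewhere. Of the 200 genes, Snhg18, Sema5a, Rida, Nipal2 and Stk3 lie on chromosome 15 between 32240568 and 35155806. Their closeness was noticed in these data and was not tested.

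Second, the trametinib libraries held fewer reads (median 7.96 M against 28.3 M with vehicle) and more genes at 0. If this depth gap produced the calls, thinning every library to the shallowest was predicted to cut the count for trametinib against vehicle below 2/3, and it fell from 2565 to 1300. The same thinning cut entinostat against vehicle, which holds no trametinib library, from 3833 to 2272, so the fall may come from lost reads alone and the prediction, as set beforehand, could not separate the cases. Depth as the whole source of the calls is argued against, since 10 more thinnings to one depth left 1318 to 1428 genes. How much of the fall came from the depth gap and how much from lost reads cannot be told apart.

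Last, interferon response genes were lower in the combination libraries (-1.12 ± 0.11, SE). Fewer T cells and macrophages as the whole source were tested with both list scores as covariates over the 18 libraries. The difference stayed at -1.13 ± 0.33, as predicted if they were not the whole source. The test cannot decide this, since in both scores every combination library lay below every vehicle library. The adjustment therefore rests on spread within groups, and part or all of the change may still go with cell make-up. A difference between animals with no link to the drugs cannot be told apart from the treatment, since the largest number of distinct column-name numbers within a group was 1. An effect of both drugs on these genes stays a hypothesis and was not tested apart from that. Mean interferon scores were 0.458 with vehicle, 0.088 with trametinib, 0.121 with entinostat and -0.658 with the combination. Each drug alone thus ran lower than vehicle, but neither passed the threshold.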

How the results depend on the processing

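Voom, thinning and the fit without libraries under 5 M reads were chosen after seeing the data. Leaving out single libraries moved no count of changed genes by over 1.5 times. The ranges were 2252 to 3048 genes for trametinib against vehicle, 3369 to 4451 for entinostat, 5842 to 6743 for the combination, 5724 to 6192 for the combination against trametinib, 4366 to 5641 against entinostat, and 2296 to 3179 for the interaction. A minimum absolute log2 fold change of 1 left 140, 95, 453, 374, 245 and 194 genes in that order, since it removes small changes. For trametinib against vehicle the count was 1420 when fitted on the compared groups only, 1566 with voom and 1300 after thinning; the cause was not tested for the first 2. After thinning, which holds fewer reads, it was 2272 for entinostat against vehicle and 1313 for the interaction. With the replicate number of the titles as a block, counts were 2177, 3593, 6013, 5823, 4696 and 2397.

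For lists past the threshold, the cause of each change below was not tested except where given. Leaving out single libraries gave 0 to 2 lists for entinostat against vehicle. Median-ratio scaling gave 2 there, and the median over members gave 2 for the interaction in place of 4, the squamous and HDAC3 corepressor calls ending. The median over members ended the cytotoxic and NK call with trametinib (adjusted p = 0.127). Scaling genes to unit SD ended the epithelial call with the combination (0.0941), and a pseudocount of 0.1 the erythroid and platelet call there (0.122). Median-ratio scaling ended the calls for alveolar type 2 and type 1 cells in the combination against entinostat (0.0583 and 0.109). For MHC class II in that comparison the median over members and unit SD did so (0.119 and 0.0888). Of the 13 calls for the combination against trametinib, cytotoxic and NK cells, checkpoints, endothelial and alveolar type 2 cells were lost without the libraries under 5 M reads (0.177, 0.145, 0.113 and 0.102). Labels permuted within replicate numbers, a paired block, gave 0 lists for trametinib against vehicle and 0 for the combination against trametinib, where 8 shared numbers allow no p under 0.00781. Camera with the preset correlation gave 10 lists for trametinib against vehicle, 5 for entinostat against vehicle and 11 for the combination against vehicle. It gave 6 for the combination against trametinib, 18 for the combination against entinostat and 11 for the interaction. With the estimated correlation it gave 0 for trametinib against vehicle, 0 for the combination against vehicle, 0 for the combination against trametinib, 1 for the combination against entinostat and 1 for the interaction. The ERK list, -0.01 with entinostat and not past the threshold, turned to a rise in camera with the preset correlation (adjusted p = 0.0246), and adjusted p was 0.809 with the estimated one. Correlations of fold changes fell with split vehicle libraries to 0.005 for trametinib and entinostat, 0.291 for trametinib and the combination and 0.490 for entinostat and the combination, where the 2 comparisons share no vehicle library. Of the alternative values of the named genes, 279 lost a call, 49 gained one and 184 changed sign without passing the threshold in either fit. The other 15033 kept their sign and their side of the threshold, which includes genes with no call.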

Other observations

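Fau, a ribosomal protein fused to a ubiquitin-like protein, chosen after its values were seen, averaged 10.6 ± 1.59 FPKM with vehicle, 10.1 ± 2.24 with trametinib, 6.07 ± 0.919 with entinostat and 1.49 ± 0.539 with the combination. The alveolar macrophage score differed from vehicle by -0.55 ± 0.23 with trametinib, 0.34 ± 0.17 with entinostat and 0.19 ± 0.28 with the combination, none past the threshold (exact permutation test, adjusted p = 0.0907, 0.223 and 0.556). Marco, a member of that list, averaged 3.55 ± 1.16, 1.28 ± 0.902, 13.4 ± 5.08 and 16.6 ± 10.5 FPKM with vehicle, trametinib, entinostat and the combination. Alveolar type 1 genes stood 0.22 ± 0.09 from vehicle with trametinib and -0.26 ± 0.10 with entinostat, neither past the threshold.

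Hsd17b14, Rps2, Atp6v0c-ps2 and Hmga1 were also higher with entinostat than with vehicle, at mean ratios of 1.73, 2.04, 1.78 and 1.91. In the same order the combination stood at 0.55, 1.14, 0.75 and 0.65 of vehicle.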
